A study of Mus musculus with 6 samples.

How the data were processed

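Polyadenylated RNA was profiled from 3 Hoxd12 knockout and 3 wild-type libraries of mouse embryonic stem cells. The deposited file of each library lists, per the file headers, the gene length, effective length, expected count, TPM and FPKM of each gene. The expected counts deposited by the authors are estimated counts that need not be whole numbers and are not normalized for depth. The deposited TPM and FPKM values are scaled by transcript length and library size, per the file headers; TPM entered alternatives and FPKM no test. The submitters' processing notes name Bowtie 0.12.2 and the builds mm8 and mm10, without saying which step used which. The quantification tool, the annotation and whether counting used strand are not given in the sources used here. All 55450 gene identifiers of the files matched GENCODE M21, whose coordinates (GRCm38) and symbols are used here. That match and not a statement of the authors is the source of the build. Groups and replicate numbers came from the sample titles.

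Expected counts were rounded to whole numbers. In R 4.3.3, edgeR 4.0.16 was run with TMM normalization, filterByExpr on the group, robust dispersions and the quasi-likelihood test with the group as the only term. Of all genes, 12891 passed the filter. P-values were adjusted by Benjamini-Hochberg and called below 0.05; an absolute log2 fold change of at least 1 set the 2-fold count. The common biological coefficient of variation was 6.74%. CPM values use TMM-scaled library sizes, except the sums over Zscan4 genes and over genes outside the filter and the limits from 3 counts, which use the library total.

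Of 36 gene lists fixed before the data were examined, the 35 with at least 5 tested members were tested with camera at a preset correlation of 0.01, and adjusted over the lists. The lists cover naive, formative and lineage genes, the 2-cell-like state, germ line, cell cycle, p53, apoptosis, Hox and HoxD genes. They also cover ERK, Wnt and LIF targets, epithelial, fibroblast and blood markers, imprinted and chromatin genes, metabolism, stress, interferon, ribosomes, mitochondria, histones and the X and Y chromosomes. Chromosome shifts are the median log2 fold change of a chromosome minus that of all other autosomes. They were tested with camera over 23 sets, with intervals from 2000 bootstrap draws over genes.

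The genes named were set by a rule written before the data were examined. It took Hoxd12, then the 8 higher and 8 lower genes with the largest change among called genes. These needed a mean of at least 5 CPM, groups that did not overlap and a symbol that is not a clone or predicted name. It then took up to 3 called members of each called list at a mean of at least 1 CPM. From the pluripotency, cell cycle, Hox, p53, ERK, fibroblast and 2-cell-like lists it took the 2 members with the smallest p. Genes named outside the rule are said to be so, and 1 gene of the rule is not reported here.

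Alternatives fixed in advance were RLE scaling, DESeq2 1.42.0, no count filter, a filter of 1 CPM in 3 libraries, a replicate block and a transcript length offset. Further ones were limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1), removal of the 20 most abundant genes, glmTreat against a 1.2-fold change, and each library left out in turn. Set tests were repeated with an estimated correlation and with fry. Directions of the lists and of chromosomes 6, 8 and 11 were also checked with DESeq2 and on TPM, without a set test. Alternatives chosen after seeing the data were a length and GC correction by loess, removal of genes of chromosomes 6, 8 and 11, and removal of the locus CT010467.1.

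The edgeR steps were tested on simulated counts of 12667 genes for the knockout and wild-type comparison. Of 50 genes changed at each size, 14% were recovered at 1.2-fold, 68% at 1.5-fold, 82% at 2-fold and 98% at 4-fold. There were 13 false calls, 9.03% of the calls, which is above the nominal 5%. Far fewer genes were changed in the simulation than the 3420 called in the data. The adjustment of p-values depends on that share, so these rates need not hold for the real comparison. Simulated groups without change gave 1 call and 0 called lists. Each gene was drawn independently there, so the lists cannot test camera where members are correlated. In the data the estimated correlation was 0.806 for cytosolic ribosomal protein genes. Depth limits precision to 3 counts, 0.478 to 0.554 CPM per library, for counting error only.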

Results

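The transcriptomes of mouse embryonic stem cells lacking Hoxd12 were compared with those of wild-type cells. Embryonic stem cells are cultured from the early embryo and can give rise to all tissues of the body. Per the labels, both groups were C57BL6 cells kept in a medium with 2i, a pair of kinase inhibitors that holds such cells in the naive state. Each group had 3 libraries, made with a stranded mRNA kit. Library totals lay between 5412577 and 6280934 expected counts. The knockout libraries held 6108034, 5412577 and 6280934 counts, and the wild-type libraries 5789159, 6263828 and 5963584. At these totals, 3 counts of a gene correspond to 0.478 to 0.554 CPM (counts scaled to library size), a limit that covers counting error only. The labels do not say whether the libraries of a group came from separate cultures or lines, so p-values measure only the spread between these libraries, which may be technical.

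The targeted gene, Hoxd12 (ENSMUSG00000001823, chromosome 2, 74675013 to 74677705, GRCm38), is a homeobox transcription factor of the HoxD cluster. It had 0 counts in all 3 knockout libraries and in all 3 wild-type libraries. Its level was therefore below what 3 counts allow in every library, 0.478 to 0.554 CPM. A loss of the transcript was not detectable at this depth, and the genotype labels could not be checked by it. The cluster neighbour Hoxd9 had 16, 17 and 9 counts in the knockout libraries and 8, 10 and 11 in the wild-type libraries. Of the 7 Hox genes tested, 0 passed edgeR's test, over all genes or adjusted over the list alone; 1 had an unadjusted p below 0.05, and DESeq2 and limma on TPM also called 0. The members with the smallest p were Hoxa7 (log2 fold change 0.76, SE 0.35, adjusted p = 0.115) and Hoxc13 (0.37, SE 0.23, adjusted p = 0.243). The Hox list as a whole was not called by camera (median 0.36, adjusted p = 0.435), nor without a count filter (median 0.52 over 35 members, adjusted p = 0.127). The set test fry, which does not compare a list with other genes, called it upward (adjusted p = 0.0421). Among 8 tested genes of the HoxD cluster and its neighbours, Nfe2l2 (0.34) and Agps (0.20) rose and Atp5g3 (-0.22) fell, 3 adjusted over the list alone (adjusted p of the list 0.550); DESeq2 and limma on TPM called 1 rise, as edgeR did without any 1 knockout library or wild-type replicate 2, and limma on TPM called 0 falls. These were named after their values were seen.

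The design text asks how the transcriptome differs between the genotypes. The maternally expressed imprinted RNA H19 fell from 112 ± 1.68 CPM in wild type to 9.26 ± 0.816 CPM in the knockout (SD, n = 3; log2 fold change -3.59, SE 0.09, adjusted p = 5.45e-25). Rpl39l, a paralogue of a ribosomal protein gene, fell from 57.9 ± 4.64 to 8.06 ± 0.590 CPM (log2 fold change -2.84, adjusted p = 1.03e-18). Zscan4f, a marker of the 2-cell-like state, fell from 11.7 ± 1.53 to 0.815 ± 0.713 CPM (-3.88, adjusted p = 1.58e-07). Gpr179, an orphan receptor gene, rose from 2.02 ± 0.504 to 12.9 ± 1.79 CPM (2.65, SE 0.24, adjusted p = 1.86e-10). H19 lies on chromosome 7 from 142575529 to 142578143 and Gpr179 on chromosome 11 from 97332109 to 97352077.

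Other genes with large rises were Mef2b (log2 fold change 1.54), Sgce (1.39), Pdf (1.31), Cpt1b (1.29), Adad2 (1.28) and the Y-linked Eif2s3y (1.19). Mef2b encodes a MADS-box transcription factor, Sgce an imprinted sarcoglycan and Cpt1b a carnitine palmitoyltransferase. Mef2b, Pdf and Adad2 lie on chromosome 8 and Sgce on chromosome 6. The other large falls were in Fam220a (-3.01), Xlr3a (-2.12), Fkbp6 (-1.92), Ak9 (-1.66) and Smtnl1 (-1.57). Adjusted p over these genes ran from 1.49e-12 for Eif2s3y to 0.00125 for Fam220a. Fam220a is uncertain, because a pair of annotated genes carries this symbol at the same locus and reads can be split between them. Its call was lost with a transcript length offset (adjusted p = 0.391), on log2(TPM + 1) (adjusted p = 0.394) and on log2(TPM + 0.1) (adjusted p = 0.466). Rpl39l and Xlr3a also belong to families with similar copies, and strand use in counting was not given in the sources used here.

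**Figure D1:**
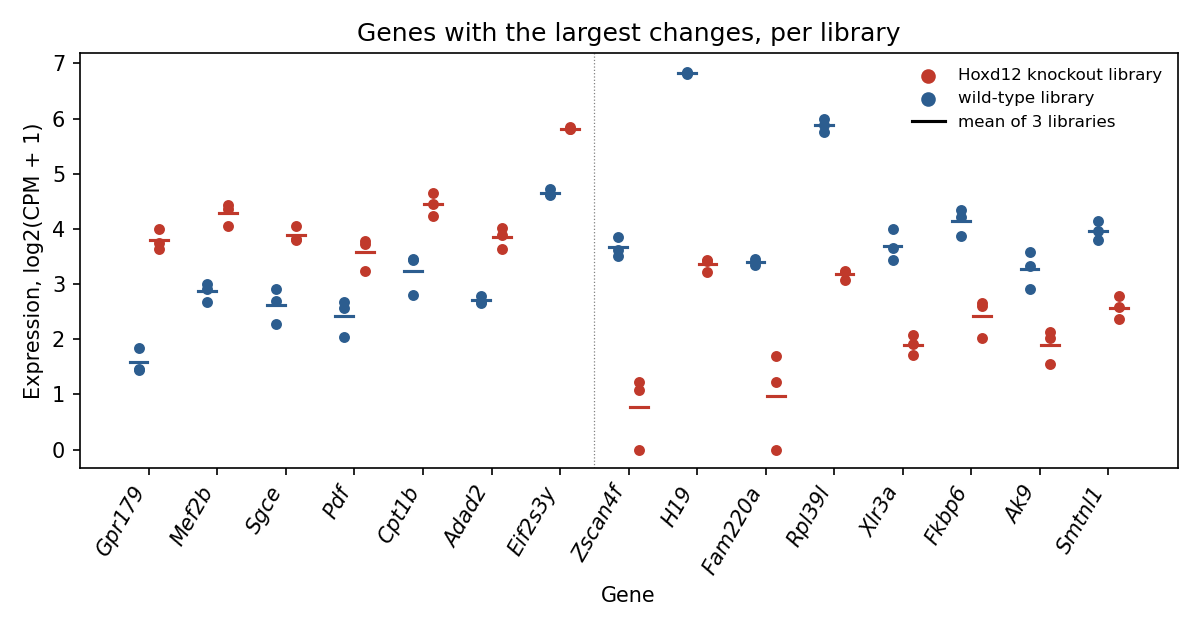
Expression of 7 of the 8 genes with the largest rises (left of the dotted line) and of the 8 with the largest falls (right), as log2(CPM + 1) in each library, with a bar for the mean of 3 libraries per group. For each gene all 3 knockout libraries lie on the same side of all 3 wild-type libraries, as the rule for choosing them required.

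Of 12891 genes tested, 3420 changed: 1559 were higher and 1861 lower in the knockout (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The median absolute log2 fold change of these genes was 0.37. Of them, 334 changed at least 2-fold, 80 higher and 254 lower. In 39.7% of tested genes the groups did not overlap, where chance gives 10%, and 3279 of the changed genes were among these. The count depended on the tool: DESeq2 called 1988 genes (701 higher, 1287 lower), and limma on log2(TPM + 1) called 1856 (1107 higher, 749 lower). On log2(TPM + 0.1) the split was 1086 higher and 738 lower, with the median of all tested genes shifted to 0.11.

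Genes of the 2-cell-like state, a rare state in stem cell cultures that resembles the early embryo, were lower in the knockout. All 7 tested members fell, the same number adjusted over the list alone, with a median log2 fold change of -2.40 (camera adjusted p = 6.86e-09; adjusted p = 0.0891 with an estimated correlation). Among them were Zscan4f (-3.88), Zscan4a (-3.56, adjusted p = 4.32e-06) and Zscan4c (-3.33, adjusted p = 3.59e-08). The Zscan4 genes are near-identical copies, so the value of each single copy is uncertain. Summed over 9 annotated Zscan4 genes, expression was 3.43 ± 0.941 CPM in the knockout and 35.4 ± 1.202 CPM in wild type (SD, n = 3).

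Germ line genes were lower as well. Of 18 tested members 9 fell and 0 rose, 9 also adjusted over the list alone, and the median was -0.43 (camera adjusted p = 4.64e-06; adjusted p = 0.0891 with an estimated correlation). The largest falls were in the X-linked genes Xlr3b (-2.86, adjusted p = 9.00e-08), Xlr3a (-2.12, adjusted p = 1.35e-08) and Rhox5 (-1.34, adjusted p = 6.98e-10).

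Targets of Wnt and beta-catenin were lower. Of 13 tested members 6 fell and 0 rose, 6 adjusted over the list alone (4 falls with DESeq2 and 3 on TPM), with a median of -0.27 (adjusted p = 0.0185; adjusted p = 0.295 with an estimated correlation). Notum, which encodes a secreted Wnt inhibitor, changed by -1.16 (adjusted p = 2.92e-09). Sp5 (-0.94, adjusted p = 0.0377) and Lef1 (-0.92, adjusted p = 0.00182) encode transcription factors induced by Wnt signalling. The call of the list was lost without knockout replicate 2 (median -0.23, adjusted p = 0.0608), without wild-type replicate 1 (-0.14, adjusted p = 0.0515) and without the genes of chromosomes 6, 8 and 11 (-0.49, adjusted p = 0.0574), within a range of 0.000575 to 0.295 over its alternatives; without knockout replicate 1 the median was -0.15. Sp5 lost its call with DESeq2 (adjusted p = 0.137) and without each library except wild-type replicate 2 (adjusted p = 0.0790 to 0.178), and in 6 other settings such as the replicate block (0.0524).

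Genes of the unfolded protein and integrated stress response were higher. Of 25 tested members 13 rose and 4 fell, 18 adjusted over the list alone, with a median of 0.21 (adjusted p = 0.00896; adjusted p = 0.252 with an estimated correlation). Examples were Vldlr (0.68, adjusted p = 0.0404), Nupr1 (0.64, adjusted p = 7.66e-08) and Chac1 (0.63, adjusted p = 0.0121). The number of falls was 2 with DESeq2 and without knockout replicate 1 or wild-type replicate 2, and 1 on TPM. The members that fell were Pdia6 (-0.25), Creld2 (-0.35), Ddit3 (-0.37) and Sdf2l1 (-0.25), named after their values were seen; Pdia6, Creld2 and Sdf2l1 encode proteins of the endoplasmic reticulum. The call of the list was lost without the genes of chromosomes 6, 8 and 11 (median 0.19 over 18 members, adjusted p = 0.137, in a range of 0.000199 to 0.252 over its alternatives), and DESeq2 did not call Vldlr (adjusted p = 0.163) or Chac1 (adjusted p = 0.0786). Vldlr was also lost without knockout replicate 2 or 3 or wild-type replicate 2 or 3 (adjusted p = 0.0594 to 0.198) and with the replicate block (0.0561), the length offset (0.108), the length and GC correction (0.0895) and both TPM fits (0.109 and 0.115), and Chac1 without knockout replicate 1 (0.0575) or wild-type replicate 2 (0.122).

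Genes of ribosomal proteins and of ribosome assembly were slightly lower. Of 68 cytosolic ribosomal protein genes 41 fell and 0 rose, 46 adjusted over the list alone, with a median of -0.14 (adjusted p = 0.00233; adjusted p = 0.772 with an estimated correlation). The largest falls were in Rpl38 (-0.36), Rpl27 (-0.34) and Rpl19 (-0.30), all on chromosome 11. A correction for transcript length and GC content moved the median to -0.01 and ended the call of the list (adjusted p = 0.708, in a range of 4.19e-11 to 0.772 over its alternatives; 15 members higher and 10 lower) and of Rpl38 (adjusted p = 0.448). Without wild-type replicate 2 the number that fell was 26. On log2(TPM + 1) the members went both ways, 9 higher and 17 lower, with a median of -0.04. The median of all genes was 0.10 on that scale. Relative to it the list lay at -0.14, against -0.16 in the main fit. Of 30 ribosome biogenesis genes 13 fell and 2 rose, 18 adjusted over the list alone, with a median of -0.12 (adjusted p = 0.0266; adjusted p = 0.282 with an estimated correlation). Pes1 (-0.37, adjusted p = 8.96e-08), Bop1 (-0.35, adjusted p = 3.78e-06) and Nop16 (-0.35, adjusted p = 4.98e-05), which act in large-subunit assembly, fell. That list lost its call with a transcript length offset (median -0.11, adjusted p = 0.0613) and without wild-type replicate 3 (-0.12, adjusted p = 0.0638, in a range of 0.000442 to 0.282 over its alternatives), with medians close to that of all libraries. On log2(TPM + 1), 3 members rose and 3 fell, and Bop1 (adjusted p = 0.161) and Nop16 (adjusted p = 0.0971) were not called. Relative to the median of all genes, ribosome biogenesis genes lay at -0.10 on that scale and -0.13 in the main fit.

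**Figure D2:**
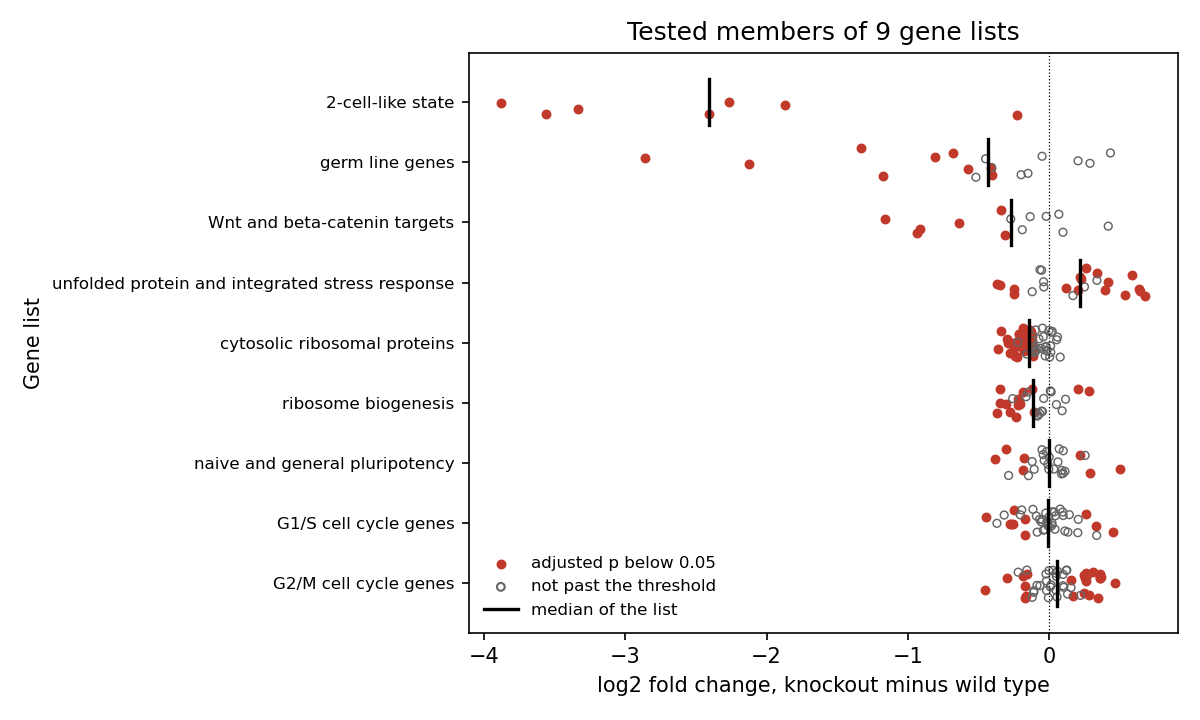
Log2 fold change, knockout minus wild type, of each tested member of the 6 gene lists called and of the pluripotency and cell cycle lists. Filled points passed the test, open points did not, and the black bar is the median of the list, -2.40 for the 2-cell-like state and 0.06 for G2/M genes.

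The series title concerns proliferation and reprogramming, so lists of cell cycle and pluripotency genes were fixed in advance. Of 42 G1/S genes 3 rose and 7 fell, 10 adjusted over the list alone (adjusted p = 0.641). DESeq2 called 1 rise and 5 falls in it and limma on TPM 4 rises and 3 falls, and edgeR called 1 rise without knockout replicate 3 or wild-type replicate 2 or 3 and 2 without knockout replicate 2 or wild-type replicate 1. Chaf1b, a chromatin assembly factor subunit, changed by -0.45 (adjusted p = 2.28e-07) and Ubr7 by 0.33 (adjusted p = 6.91e-05). Of 52 G2/M genes 17 rose and 7 fell, 27 adjusted over the list alone, and the list was not called (median 0.06, adjusted p = 0.153); the median was 0.03 without knockout replicate 1 and 0.09 without knockout replicate 2. DESeq2 called 7 rises and 5 falls in it, and limma on TPM 13 rises and 1 fall. Tubb4b, a tubulin gene, changed by -0.46 (adjusted p = 9.18e-10) and the chromatin protein gene Hmgb2 by 0.37 (adjusted p = 1.64e-07). Hmgb2 lies on chromosome 8, in a 10 Mb window whose median was 0.41 above that of the other autosomes. Its rise is therefore not separate from that of its neighbours. Without a count filter the G2/M list passed (adjusted p = 0.0401, in a range of 0.0136 to 0.382 over its alternatives). Of 29 cyclins, CDKs and CDK inhibitors 2 rose and 5 fell, 6 adjusted over the list alone (adjusted p = 0.435). DESeq2 called 1 rise and 4 falls, limma on log2(TPM + 1) 3 rises and 4 falls, and edgeR 1 rise without knockout replicate 1 or 2 or wild-type replicate 1 or 2. The genes that rose, named after their values were seen, were Cdkn1b (1.00) and Cdkn2a (0.29), which encode CDK inhibitors. The genes that fell were Ccnd1 (-0.64), Ccnd3 (-0.51), Ccne1 (-0.45), Cdk6 (-0.31) and Ccnb1 (-0.17).

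The list of naive and general pluripotency genes was not called (27 tested, median -0.005, adjusted p = 0.997), with 7 calls adjusted over the list alone. Its mean was also below 0, while the test's direction was upward. Zfp42 (0.29, adjusted p = 1.43e-05), Tet2 (0.50) and Jarid2 (0.21) rose. Klf5 (-0.31, adjusted p = 7.17e-05), Nanog (-0.39), Sall4 (-0.19) and Tcl1 (-0.18) fell, and Klf5 was not called on log2(TPM + 1) (adjusted p = 0.164) or log2(TPM + 0.1) (adjusted p = 0.162). DESeq2 called 3 falls in this list, limma on log2(TPM + 1) 1 and on log2(TPM + 0.1) 0, while each called 3 rises. Without knockout replicate 2 the list had 7 rises, and without knockout replicate 3 it had 1 fall. Apart from Zfp42 and Klf5, these genes were named after their values were seen. Of 18 genes of formative and primed pluripotency 1 rose and 6 fell, 7 adjusted over the list alone (adjusted p = 0.435). The median, -0.05, ran from -0.12 without knockout replicate 1 to 0.01 without wild-type replicate 2. The set test fry, which does not compare a list with other genes, called the formative list (adjusted p = 0.0418) and the ERK list (0.0437) downward. Of 15 LIF and STAT3 targets 5 fell and 0 rose, 7 adjusted over the list alone (adjusted p = 0.137), with 3 falls on TPM; without a count filter it passed (adjusted p = 0.0385, in a range of 0.00747 to 0.382 over its alternatives). Of 16 immediate targets of the ERK pathway 2 rose and 4 fell, 6 adjusted over the list alone (adjusted p = 0.497; 1 rise and 4 falls with DESeq2 and without knockout replicate 1 or wild-type replicate 2 or 3, and 1 rise and 2 falls on TPM), with Etv4 at -0.87 (adjusted p = 5.07e-08) and Ccnd1 at -0.64 (adjusted p = 3.42e-06).

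In edgeR's fit of all libraries camera called none of the lineage lists. With the length and GC correction the primitive streak list was called (adjusted p = 0.0451, in a range of 0.000235 to 0.540 over its alternatives). Without a count filter the epithelial list was (adjusted p = 0.0421, in a range of 0.00618 to 0.382). With fry on all libraries the primitive streak (adjusted p = 0.000235), epithelial (0.00618) and mesenchymal (0.0136) lists were called. Members named here, apart from Vim and Fn1, were chosen after their values were seen. Of the 5 tested primitive streak and mesendoderm genes Lefty1 (0.36), Lefty2 (0.46) and Nodal (0.24) rose, which encode ligands and antagonists of Nodal signalling, and Gsc (-1.35) fell, 4 adjusted over the list alone; the median was 0.24, the mean -0.07 and the test's direction upward (adjusted p = 0.137). Its median was 0.02 without wild-type replicate 1 and 0.10 without wild-type replicate 2, and DESeq2 called 2 rises and 0 falls; the fall was also lost without knockout replicate 1 or 2 or wild-type replicate 2 or 3, and 2 rises were called without knockout replicate 2. Of 10 primitive endoderm genes Gata4 (1.10), Col4a1 (0.54), Col4a2 (0.43) and Lamc1 (0.19) rose and Sparc (-0.20) fell, 5 adjusted over the list alone (adjusted p = 0.550). For this list limma on TPM called 0 members and DESeq2 1 rise and 1 fall, and edgeR 1 rise without knockout replicate 1 and 2 rises without knockout replicate 3 or any of the wild-type libraries. Without the genes of chromosomes 6, 8 and 11, 6 members remained, of which 2 rose and 0 fell. The median of the primitive endoderm list, 0.14, was then -0.05, and it was -0.02 without knockout replicate 1. Of 12 trophectoderm genes Tead4 (0.41) rose and Ascl2 (-0.60) fell, 2 adjusted over the list alone (adjusted p = 0.723), where DESeq2 and limma on TPM called 0, as edgeR did without knockout replicate 3 or wild-type replicate 2; without knockout replicate 2 it called 2 falls. Of 5 neuroectoderm genes Tubb3 (-0.40) fell, 1 adjusted over the list alone (adjusted p = 0.723), where limma on TPM called 0. Of 20 epithelial genes 6 rose, among them the cell adhesion genes Cdh1 (0.43) and Epcam (0.36), and Grhl2 (-0.96) and Cldn3 (-0.48) fell, 8 adjusted over the list alone (adjusted p = 0.153); DESeq2 called 5 rises and limma on TPM 4, both called 0 falls, and edgeR 0 falls without wild-type replicate 1 and 1 without knockout replicate 1 or 3 or wild-type replicate 2 or 3. Of 13 mesenchymal and embryonic fibroblast markers 1 rose and 3 fell, 5 adjusted over the list alone (adjusted p = 0.202); the median, -0.42, was -0.25 without wild-type replicate 1 and -0.07 on log2(TPM + 1), and the falls were 2 with DESeq2, on TPM and without knockout replicate 2 or wild-type replicate 1. Vim, an intermediate filament gene, changed by -0.86 (adjusted p = 1.99e-13) and Fn1, the fibronectin gene, by 0.54 (adjusted p = 2.53e-11), and Thy1 (-0.97) and S100a6 (-1.46) fell. Of 5 tested blood and endothelial markers 0 passed edgeR's test and 0 adjusted over the list alone (adjusted p = 0.645); 1 had an unadjusted p below 0.05, and DESeq2 and limma on TPM called 0.

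Stress, metabolic and chromatin lists other than the unfolded protein response were not called by camera in that fit either. The set test fry, which does not compare a list with other genes, gave further calls. It called glycolysis (adjusted p = 0.00984), hypoxia (0.0254) and DNA methylation enzymes (0.0437) upward, and heat shock genes (0.0418) downward. Members named here, apart from Pltp and Rps27l, were chosen after their values were seen. Of 29 p53 target genes 8 rose and 4 fell, 17 adjusted over the list alone (adjusted p = 0.245; DESeq2 called 2 rises and 2 falls, limma on log2(TPM + 1) 8 rises and 1 fall, and edgeR 4 rises without knockout replicate 1 and 5 without wild-type replicate 2 or 3), with Pltp at 0.51 (adjusted p = 2.86e-10) and Rps27l at -0.30 (adjusted p = 4.06e-06). Of 28 apoptosis regulators 5 rose and 6 fell, 11 adjusted over the list alone; median and mean were above 0 while the test pointed downward (adjusted p = 0.870), and single libraries turned these signs; 2 rises were called without knockout replicate 1 or 3 or wild-type replicate 3, and 3 without wild-type replicate 2, and falls were 4 without the latter. DESeq2 called 1 rise and 6 falls, and limma on TPM 2 rises and 1 fall. Of 23 glycolysis genes 11 rose and 2 fell, 13 adjusted over the list alone (adjusted p = 0.160), with 6 rises under the length offset and 1 fall on TPM. Of 19 hypoxia genes 6 rose and 1 fell, 7 adjusted over the list alone (adjusted p = 0.137), with 3 rises by DESeq2 and on TPM; without a count filter the list passed (adjusted p = 0.0401, in a range of 0.0254 to 0.643 over its alternatives). Of 24 cholesterol synthesis genes 4 rose and 2 fell, 6 adjusted over the list alone (adjusted p = 0.550); DESeq2 called 2 rises and 1 fall, limma on TPM 0 falls, and edgeR 1 fall without knockout replicate 1 or 3 or wild-type replicate 2 or 3. Of 15 heat shock and immediate early genes 6 fell, among them Hspb1 (-0.48) and Hspe1 (-0.32), which encode heat shock proteins, 6 adjusted over the list alone (adjusted p = 0.324), with 2 falls on TPM. Of 12 interferon response genes B2m (0.42) rose and Oas1a (-1.03), Ifitm2 (-0.18) and Ifitm3 (-0.15) fell, 4 adjusted over the list alone, with a median of 0.04, a mean of -0.02 and a downward test (adjusted p = 0.870); without wild-type replicate 1 the median was 0.001. DESeq2 called 0 rises and 2 falls in it and limma on TPM 1 rise and 1 fall; edgeR called 0 rises without knockout replicate 1 and 2 without wild-type replicate 3. Of 30 Polycomb subunits 7 rose, among them Ezh2 (0.37), and Epop (-0.60) and L3mbtl2 (-0.18) fell, 9 adjusted over the list alone (adjusted p = 0.326); limma on TPM called 3 rises and 1 fall and DESeq2 5 rises and 1 fall, and edgeR 1 fall without wild-type replicate 1 or 2. Of 15 enzymes of DNA methylation and demethylation 4 rose, among them Tet1 (0.35) and Dnmt1 (0.25), and Dnmt3b (-0.69) and Trim28 (-0.28) fell, 6 adjusted over the list alone (adjusted p = 0.550), with 1 rise and 2 falls on TPM. Of 15 mitochondrially encoded genes mt-Nd1 (-0.17) fell, 0 adjusted over the list alone (adjusted p = 0.641); without wild-type replicate 2 the number was 5 and without knockout replicate 2 it was 2, and it was 0 on TPM and without knockout replicate 1 or 3 or wild-type replicate 1. Of 11 replication-dependent histones Hist1h3a (-0.96) and Hist1h3c (-0.76) fell, 2 adjusted over the list alone (adjusted p = 0.230), and the number was 4 without wild-type replicate 2, 3 without knockout replicate 2, and 1 with DESeq2 and without wild-type replicate 1 or 3. Of the 35 lists tested, 6 were called with the preset correlation and 0 with an estimated correlation. On log2(TPM + 1), where the median of all genes was 0.10, the medians of the naive, formative, trophectoderm, G1/S, cyclin, ERK and heat shock lists turned positive.

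Genes of 3 autosomes moved together. Genes on chromosomes 6 and 8 were higher in the knockout, and genes on chromosome 11 lower, relative to the other autosomes. The median log2 fold change of a chromosome minus that of the other autosomes was 0.15 for chromosome 6 (95% bootstrap interval 0.12 to 0.18, adjusted p = 2.94e-05). It was 0.16 for chromosome 8 (0.14 to 0.19, adjusted p = 2.60e-06) and -0.15 for chromosome 11 (-0.17 to -0.14, adjusted p = 9.27e-06). All 3 calls held with an estimated correlation (adjusted p = 0.00337, 0.00289 and 0.0104). On chromosome 6, 183 of 600 tested genes rose and 47 fell; on chromosome 8, 212 of 703 rose and 42 fell. On chromosome 11, 293 of 1050 fell and 34 rose. The other 16 autosomes lay between -0.04 and 0.03. These 3 chromosomes hold 811 of the changed genes, 23.7% of the changed and 18.3% of the tested genes. The 10 tested genes within 1 Mb of Hoxd12 were not called as a set (0.04, adjusted p = 0.736).

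**Figure D3:**
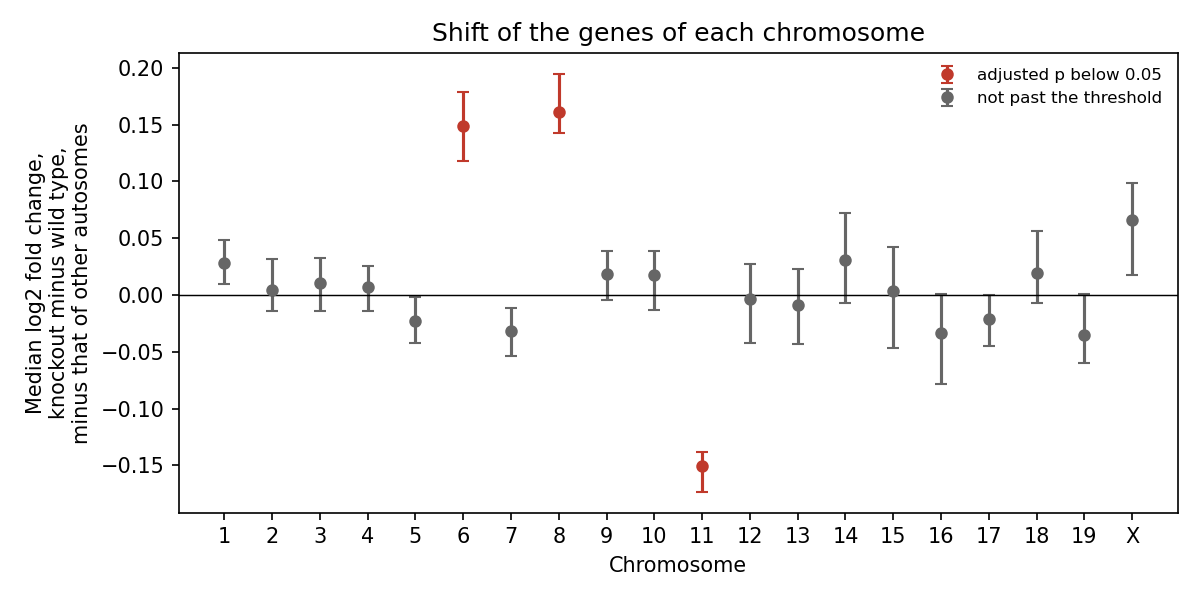
Median log2 fold change, knockout minus wild type, of the tested genes of each chromosome minus the median of the other autosomes, with 95% bootstrap intervals over genes. Chromosomes 6 and 8 lie at 0.15 and 0.16 and chromosome 11 at -0.15, while the other 16 autosomes lie between -0.04 and 0.03.

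Y-linked genes were expressed in both groups, and Xist, the RNA that coats the inactive X chromosome of female cells, had 1 to 5 counts per library. Eif2s3y rose from 24.3 ± 0.933 to 55.4 ± 0.926 CPM, and Ddx3y, named after its values were seen, fell from 11.1 ± 0.971 to 3.69 ± 0.569 CPM (SD, n = 3; log2 fold change -1.57, adjusted p = 7.35e-07). Of 12 tested Y genes 6 rose and 1 fell, and the Y set was called (shift 0.43, interval -0.30 to 6.51, adjusted p = 2.04e-05; adjusted p = 0.0554 with an estimated correlation). Its shift moved to 1.24 without wild-type replicate 1, 1.17 without wild-type replicate 2 and 0.82 without knockout replicate 2. Among the genes that rose, Gm28304 and Gm29256 had identical counts, 23, 11 and 14 against 0 in each wild-type library. The same reads may therefore enter the Y set more than once. Apart from Eif2s3y, the Y genes that rose carry predicted names. Kdm5d (-0.14, adjusted p = 0.701) and Uty (0.38, adjusted p = 0.452), named after their values were seen, did not pass edgeR's test. A rise of Y genes in general was thus not shown. The X chromosome was not called (0.07, adjusted p = 0.736). Of 10 genes of X inactivation and dosage Pgk1 (0.19), Dusp9 (0.27) and Rlim (0.20) rose and Ftx (-0.48) and Klhl13 (-0.91) fell, 5 adjusted over the list alone (adjusted p = 0.759), named after their values were seen; limma on TPM called 1 rise and 2 falls. The fixed list of Y-linked genes had under 5 tested members and was not tested as a list.

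Libraries fell by group: the first principal component, with 46.0% of the variance of log2 CPM, separated knockout from wild type. The second, with 16.0%, set knockout replicate 2 apart. That library held 88170 counts of the ribosomal RNA locus CT010467.1, where the others held 6383 to 8267. Correlations across genes of log2 CPM were 0.982 to 0.985 within groups and 0.969 to 0.973 between them; genes are not independent replicates.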

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

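Outside the main measurement, the deposited gene lengths, which weight the isoforms of a gene by their use, differed between the groups for 5 of 7239 genes examined (limma on log2 length, adjusted p below 0.05; mean of at least 10 CPM). Eif4g2, a translation regulator, had a mean length of 2721 ± 47.4 bases in the knockout and 4064 ± 10.004 in wild type (SD, n = 3; adjusted p = 0.00237). Esrra was shorter as well (2053 ± 2.66 against 2242 ± 0.762 bases). Rpn2 (1574 ± 34.5 against 1226 ± 15.6), Bcl7b (1577 ± 25.7 against 1336 ± 10.1) and Tead1 (9464 ± 58.7 against 7380 ± 207) were longer. Only the real one of the 10 splits of the 6 libraries, 1 in all, gave as many genes, and the highest other split gave 1. The other splits put both genotypes on each side, which adds any group difference to the spread, so their counts are no baseline for chance. With 10 splits the share cannot fall under 0.1, so it cannot reach 0.05.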

How the results depend on the processing

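The length and GC correction and the removal of genes of chromosomes 6, 8 and 11 or of CT010467.1 are tests chosen after the results were seen; they gave 3113, 2534 and 3425 changed genes, and 2622 of the 3113 were shared with the 3420 reported, 2610 of them in the same direction. That count was 1988 with DESeq2, 1856 on log2(TPM + 1), 1824 on log2(TPM + 0.1) and 806 with glmTreat against a 1.2-fold change; glmTreat tests a stricter hypothesis, and for the others the cause was not tested. The 2-fold count, 334, was 108 on log2(TPM + 1), a scale that shrinks the changes of low genes. Leaving out each library gave 2615 to 3210 changed genes. Called lists numbered 6, against 17 with fry, 0 with an estimated correlation and 10 without a count filter, which added the G2/M, LIF, epithelial and hypoxia lists. Of the 6, the cytosolic ribosomal protein list was not called by fry (adjusted p = 0.0880). The G2/M list was called without a filter (median 0.056, adjusted p = 0.0401) and with fry (median 0.056, adjusted p = 0.0136), which does not compare a list with other genes; the cause was not tested. With the length and GC correction the primitive streak list was called (adjusted p = 0.0451). The shifts of chromosomes 6, 8 and 11 kept their direction under each alternative run on them, and their call under each that has a test; with each library left out they ran from 0.14 to 0.16, 0.16 to 0.18 and -0.16 to -0.15. Of the values of named genes under alternatives, 779 kept their direction and their side of the threshold, 35 lost their call and 0 reversed. The replicate block gave 3353 changed genes and 6 lists. Same-numbered libraries deviated together only weakly (correlations across genes 0.004, 0.041 and 0.024), and not every library correlated best with its own number. The labels do not say whether a number is a shared batch, so pairing was neither shown nor excluded. Depth limits values near 0.478 to 0.554 CPM.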

Other observations

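The tests of explanations for the chromosome shifts, the count of splits for changed genes and the length and GC correction were chosen after the result was seen. The camera test of the chromosomes and its count of splits were fixed beforehand. Imprinted genes moved in both directions. Of 31 tested members 10 rose and 5 fell, 17 adjusted over the list alone, with a median of 0.09, a mean of -0.04 and an upward test (adjusted p = 0.550); the median was 0.01 without knockout replicate 3, and DESeq2 called 8 rises and 2 falls. These genes were named after their values were seen, apart from H19 and Sgce. Next to the fall of H19 (-3.59), its neighbour Igf2, a growth factor gene, rose from 5.12 ± 1.07 to 10.2 ± 0.956 CPM (log2 fold change 0.97, adjusted p = 0.000449). The maternally expressed RNAs Meg3 (0.66, adjusted p = 4.57e-13), Rian (0.75) and Mirg (0.69) of chromosome 12 rose. On chromosome 6 Sgce (1.39) and Mest (0.60) rose, while Peg10, adjacent to Sgce, was at -0.01 (adjusted p = 0.918).

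On the Y chromosome, the RNA gene Gm29206 (61556222 to 61583931) had 39, 31 and 20 counts in the knockout libraries and 0 in each wild-type library. That is at least 30-fold higher against 3 counts over the whole wild-type group (0.167 CPM), a lower limit than 3 counts per library. Gm29343 (61789649 to 61815122) had 42, 63 and 53 counts against 0, 2 and 0. Both were chosen after their values were seen, and repeated Y sequence makes the source of their reads uncertain.

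Genes of chromosomes 6 and 8 were higher and those of chromosome 11 lower in the knockout, and the tables argue against a length or GC trend as the whole cause, since after its correction the smallest shift was 0.138 in size. They argue against a few strongly regulated genes, because at least 68.3% of all tested genes of each chromosome lay on the shifted side (exact binomial interval 64.4% to 72.0% on chromosome 6). This share in part restates the shifted medians by which the chromosomes were picked, and the interval treats genes as independent. The test of shares replaced one written after the shifts were seen but before its own value was. The earlier test asked for a shift above 0.05 among the genes that did not pass, which picks genes by the outcome. It was met on chromosomes 8 (0.078) and 11 (-0.088) and missed on 6 (0.047). An extra copy in every cell of one line, expressed in proportion, would shift a chromosome by 0.58, and the highest bound was 0.195. A candidate explanation that stays open is a changed copy number in a share of the cells. Of the 41 windows of 10 Mb, 100% went the same way, but their shifts were uneven. They ran from 0.05 to 0.40 on chromosome 6, 0.10 to 0.41 on chromosome 8 and -0.24 to -0.03 on chromosome 11. At 1 extra copy the chromosome medians alone would correspond to 21.7% to 23.7% of cells. Gain or loss, the line it is in and any link to Hoxd12 were not tested.

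The lower 2-cell-like genes were weighed against reads split between Zscan4 copies. That is argued against, since the summed Zscan4 CPM of the highest knockout library was 0.129 of the lowest wild-type library. A smaller share of cells in a 2-cell-like state stays open. The 21 list members outside the filter, pooled, stood at 3.31 ± 0.196 CPM in the knockout and 11.9 ± 4.23 in wild type (SD, n = 3). That ratio, 0.279, met the prediction set for it, but is no independent support. The pool holds Zscan4b, Zscan4d and Zscan4e, which also enter the Zscan4 sum, and the filter depends on the same counts. Sp110, also in the pool, went the other way, with 7, 5 and 12 knockout counts against 6, 4 and 3. Lower expression per cell stays open, and so does a difference between cell lines, which the design does not separate from the genotype.

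The lower ribosomal protein genes may reflect how the libraries depend on transcript length. The fifth of genes with the shortest transcripts had a median log2 fold change of -0.15 and the fifth with the longest 0.10. The length and GC correction moved the ribosomal median from -0.14 to -0.01. That correction removes both trends together, so the move cannot be put down to length alone. Among 10000 lists matched on length and expression, 5.33% had a median at or below that of the ribosomal protein genes, close to the 5% bound set beforehand. Matched genes were longer (median 1378 against 1114.5 bases), so the match was incomplete. A biological decrease stays open, as untested.

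Counts were compared over the 10 splits of the 6 libraries, too few for a share under 0.05. The real split called 3420 genes and the highest other 2; for 2-fold changes 334 and 2, and for lists 6 and 3, so 1 split of 10 reached each real count. For chromosome sets 3 of the 10 splits reached the real 4, and the highest other was 4. The other splits put both genotypes on each side, in unequal numbers, and their largest autosomal shift was 0.06, against 0.16. A difference between the genotypes then adds to the spread within each side and lowers the calls. The counts of the other splits are therefore no baseline for chance.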
